A study of Homo sapiens with 8 samples.

How the data were processed

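Polyadenylated RNA was sequenced from IMR90 cells, an established line of human fetal lung fibroblasts, in 8 libraries. In each of 4 replicates, 60000 cells received 300000 pieces of the added material for 20 hours. The material was either inert plastic beads (4 libraries, named Beads) or what the labels call SCAFs (4 libraries), which had been sorted by flow cytometry out of GFP-labelled senescent cultures of the same line. The beads had gone through that sorting procedure too. The series' design text calls the 4 replicates independent and biological, and does not state whether a replicate number marks a shared culture or day.

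The deposited table holds raw read counts per Ensembl gene, 1 column per library, with 60564 genes and no summary lines for unassigned reads. Libraries were stranded, with dUTP in the second strand, per the labels' protocols. The tools bcl2fastq 2.17.1.14, STAR 2.5.3a and HTSeq 0.6.1p1 and the build hg38 come per the submitters' processing notes. The annotation release, the strand setting of the counting and the read filters are not given in the sources used here. Antisense and overlapping genes are therefore named as uncertain where they share exons with a reported gene. Gene symbols were matched by Ensembl identifier for 60295 of the 60564 genes. Coordinates, GC content and transcript length came from GENCODE 29 on the same assembly, in which 58457 of the identifiers were found.

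Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the group, which left 14727, libraries were scaled by TMM, and the quasi-likelihood F test was run with robust estimation. P-values were adjusted by the Benjamini-Hochberg method over the 14727 genes, with a threshold of 0.05. Fold changes are log2 ratios of SCAFs over Beads. Their standard error (SE) is the absolute log2 ratio divided by the square root of the F statistic of the test. Levels are CPM on TMM-scaled totals as mean ± SD of 4 libraries. The design, the gene lists, the rule for named genes and all alternatives not marked otherwise were fixed before the data were examined. The design had the group alone. A fit with the replicate number as a block was planned as its alternative.

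Whether the replicate numbers pair the libraries was checked from deviations of log2 CPM from the group means, before the calls of the fits were compared. The correlation of these deviations across genes lay between 0.177 and 0.221 for the 4 pairs with the same number. It lay between 0.153 and 0.201 for libraries of other numbers within replicates 1 and 2 or within 3 and 4, and between -0.213 and -0.168 across these sets. Every same-number pair exceeded 0.1, so the numbers were taken as pairs, a pairing that comes from the values and not from the labels. Libraries of other numbers within a set exceeded 0.1 too, so this criterion does not tell pairs from sets. Only 5 of the 8 libraries were closest to the library of their own number, so the block may stand for the 2 sets more than for 4 pairs, and counts over 4 pairs are to be read with that limit. Libraries of 1 group differed by more than sampling noise. Over the 12 within-group pairs the mean chi-square per degree of freedom was 2.24 to 18.2. It was 2.24 to 3.60 within the 2 sets and 9.96 to 18.2 across them. None was therefore counted as the same library deposited again, but libraries of 1 shared culture are not excluded. If the libraries of a set share a culture, standard errors and p-values with the block and SDs over pairs may be too small. The same holds for p-values of fits within the sets, with a term for the sets and of the interaction between set and treatment. The coefficient of biological variation in edgeR was 2.77% with the block and 5.91% without it.

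A total of 33 gene lists with 989 entries was written from general knowledge. Lists with at least 5 tested genes (31 of 33) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 31. Camera with an estimated correlation and fry were run as alternatives. Beside each list stands the number of its members past the threshold over all genes and adjusted over the list alone. In the list entries, 5 symbols had no match in the name table and were not analysed here. A further 4 lists were written after the results had been seen and are used only among the closing observations.

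For the named genes, the rule took genes from those past the threshold. Among genes past the threshold with an average of at least 2 log2 CPM and no overlap between the 4 libraries of each group, it took the 10 largest changes in each direction and the 5 smallest p-values. From each list it took up to 3 members past the threshold. For a list with a camera call and no such member it took the 2 members of smallest p. Members named only from the fit with the block were added after the data had been seen, as up to 4 members of smallest p per list.

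Per-library measures were compared with exact two-sided permutation tests, whose smallest p for 4 against 4 is 0.0286. Alternatives were DESeq2 1.42.0 size factors, total counts alone, the DESeq2 test, limma-voom, no filter, a filter of 1 CPM in 4 libraries, no robust estimation, and each library left out in turn. A term for replicates 1 and 2 against 3 and 4, fits within each of these sets, the block in other tests or with a GC and length correction, and the block without each replicate number were chosen after seeing the data.

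The fits were tested on simulated data of the comparison of SCAFs with Beads, drawn for 14727 genes with 200 changed. Without the block, 20% of the genes changed 1.15-fold, 34% at 1.25-fold, 70% at 1.5-fold and 80% at 2-fold were recovered, with 0 false calls among 102. With the block, the shares were 56%, 60%, 86% and 94%, with 7 false calls among 155. In a draw with no gene changed, edgeR called 7 genes with the block and 0 without it. The means and dispersions of the draws came from the fit with the block, so its higher recovery was built into the simulation. Camera called 5 of 5 shifted lists and 0 of 15 others. These lists were random and their genes were drawn independently of each other. The estimated inter-gene correlation of the real NRF2 list was 0.73 (block 0.28) and that of the mitotic list 0.86 (block 0.56). The simulation therefore cannot show how often camera calls real lists falsely. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.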

Results

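The transcriptomes of IMR90 fibroblasts were compared after 20 hours with SCAFs or with inert beads, 4 libraries per group. The comparison addresses how fibroblasts respond to material sorted from senescent cells of their own line, with handled beads as the control. The libraries held between 25842654 counts (SCAFs 1) and 37080163 counts (SCAFs 3). The mean was 32.3 ± 4.14 M counts (SD, n = 4) with Beads and 32.3 ± 4.69 M counts with SCAFs, and no difference was found (exact permutation p = 1, two-sided, adjusted p = 1 over 4 library measures). At this depth a count of 3 corresponds to between 0.0809 and 0.116 CPM. Mitochondrially encoded genes took 1.31 ± 0.122% of the counts with Beads and 1.24 ± 0.0668% with SCAFs (exact permutation p = 0.486, adjusted p = 0.762). Without Beads 1 the difference between these means, -0.0688 percentage points, was -0.0114. The 10 most abundant genes took 8.02 ± 0.242% and 7.63 ± 0.211% (exact permutation p = 0.0857, adjusted p = 0.343), and were lower with SCAFs in 4 of 4 pairs. Genes with a count numbered 22910 ± 414 and 23142 ± 751 (exact permutation p = 0.571, adjusted p = 0.762).

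**Figure D1:**
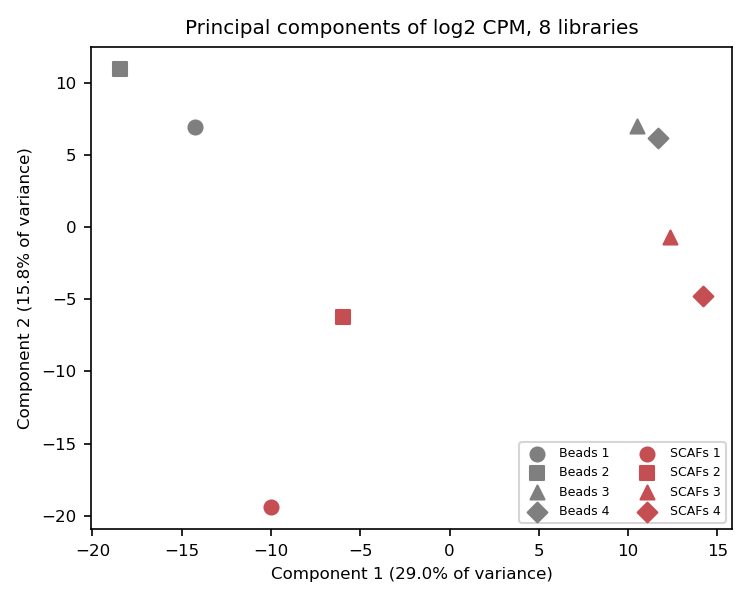
Principal components of log2 CPM of the 8 libraries, with component 1 on the horizontal axis and component 2 (15.8% of the variance) on the vertical axis. Each point is a library, grey for Beads and red for SCAFs, with a symbol per replicate number, and replicates 1 and 2 lie to the left of replicates 3 and 4 in both groups.

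The libraries of replicates 1 and 2 lay apart from those of replicates 3 and 4 in both groups, along the first principal component. With the treatment as a term, edgeR called 3744 genes between these sets, 1759 higher and 1985 lower in replicates 3 and 4. Proliferation genes made up part of the difference: 39 of 40 mitotic genes and 35 of 40 S phase genes were called higher in replicates 3 and 4. Of the NRF2 list, 21 of 25 genes were called lower there, as were 24 of 39 matrix genes other than collagens. Each set held 2 libraries of each group, so every comparison below could also be made within them.

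Libraries of fibroblasts given SCAFs held more mRNA of TGM2, a transglutaminase that crosslinks proteins, of RGS5, a regulator of G-protein signalling, and of DCC, a netrin receptor. The same libraries held less mRNA of HMOX1, the haem oxygenase, and of IGFBP3, which binds insulin-like growth factors. The matrix protein periostin (POSTN) and tissue factor (F3), which starts coagulation, were lower too. RNA carried over with SCAFs was not told apart from RNA of the fibroblasts. TGM2 rose by 35.8%, from 318 ± 14.7 CPM with Beads to 431 ± 14.9 CPM with SCAFs (log2 change 0.44 ± 0.039 SE). IGFBP3 fell by 34.6%, from 334 ± 35.9 CPM with Beads to 219 ± 9.56 CPM with SCAFs (log2 change -0.61 ± 0.07). The changes were small: the median absolute log2 change of the genes called was 0.30 without the block and 0.15 with it.

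By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 33 of 14727 genes changed, 15 higher and 18 lower with SCAFs, and 1080 had an unadjusted p under 0.05. With the replicate number as a block the same test called 834, of which 383 were higher and 451 lower. A term for the replicate sets in place of the block called 907, so the gain need not come from the pairs. With the block, DESeq2 called 358 genes, and edgeR 453 without replicate 4, so the counts with the block below depend on the test and on the replicates. Of the 33 genes, 32 were called in both fits, all in the same direction, and the exception was IGFBP3 (adjusted p = 0.0905 with the block). Within replicates 1 and 2 alone 580 genes were called and within replicates 3 and 4 alone 356. These lists shared 193 genes, 191 of them with the same sign. Independent lists of these sizes would share 14.0 if every gene were equally likely to be called. Genes with higher counts are easier to call in both sets, so the overlap by chance may be larger. The 4 SCAFs libraries lay outside the range of the 4 Beads libraries for all 33 genes and for 730 genes in all (4.96%, where chance gives 2.86%). Without the block, leaving out a library gave 7 (Beads 1), 21 (Beads 2), 26 (Beads 3), 20 (Beads 4), 9 (SCAFs 1), 8 (SCAFs 2), 8 (SCAFs 3) or 3 calls (SCAFs 4).

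Among the genes that rose, TGM2 (ENSG00000198959, chromosome 20, 38127387 to 38166578) on hg38, as all coordinates here, had an adjusted p of 6.60e-04 by edgeR. RGS5 (ENSG00000143248, chromosome 1, 163111121 to 163321791) went from 5.58 ± 0.347 CPM with Beads to 9.15 ± 0.192 CPM with SCAFs (log2 change 0.71 ± 0.076, adjusted p = 0.00303), and a second annotation of the same name overlaps its exons on the same strand. DCC (ENSG00000187323, chromosome 18, 52340172 to 53535903) stood at 7.66 ± 0.477 CPM with Beads and 11.5 ± 0.56 CPM with SCAFs (log2 change 0.58 ± 0.073, adjusted p = 0.00996). TFPI2, a protease inhibitor of the matrix, rose by 0.33 on the log2 scale (adjusted p = 0.00996) and shares exons with antisense annotations. SOCS2, a suppressor of cytokine signalling, rose by 0.37, the pyruvate dehydrogenase kinase PDK1 by 0.32, the transcription factor ETV1 by 0.33 and the junction protein JUP by 0.35. SSX2IP rose by 0.26 and the dynein light chain DYNLT3 by 0.26. The secreted guidance factor SEMA3A rose by 0.24 and the collagen-binding integrin subunit ITGA2 by 0.19. All of these genes were higher with SCAFs in 4 of 4 pairs, with adjusted p by edgeR from 6.60e-04 to 0.0479. Since their libraries do not overlap between the groups, any pairing would give 4 of 4. TGM2, PDK1, SOCS2 and DCC have antisense annotations over their exons, and whether the counting used strand is not given in the sources used here.

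Among the genes that fell, HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214) stood at 61 ± 4.64 CPM with Beads and 46.5 ± 1.72 CPM with SCAFs (log2 change -0.39 ± 0.053, adjusted p = 0.0152 by edgeR). POSTN (ENSG00000133110, chromosome 13, 37562583 to 37598844) stood at 356 ± 25.3 CPM with Beads and 273 ± 14.7 CPM with SCAFs (log2 change -0.38 ± 0.052, adjusted p = 0.0152). F3 (ENSG00000117525, chromosome 1, 94529225 to 94541800) had a log2 change of -0.42 ± 0.065, and the metalloprotease ADAM12 one of -0.46 ± 0.075. IGFBP3 (ENSG00000146674, chromosome 7, 45912245 to 45921874) was lower in every pair, with log2 changes of -0.79 in replicates 1 and 2 and -0.43 in replicates 3 and 4. That difference between the sets passed an interaction test in edgeR (adjusted p = 1.31e-07), whose p-value may be too small if libraries of a set share a culture. The log2 change was -0.38 for NREP, -0.33 for the focal adhesion adaptor LIMS2, -0.30 for EML5 and -0.25 for the vasodilator peptide gene ADM. It was -0.23 for tropomyosin TPM1, -0.20 for the matricellular gene CCN1 and -0.26 for the smooth muscle actin ACTG2, whose value is uncertain because actin paralogs share sequence. These genes were lower with SCAFs in 4 of 4 pairs, again fixed by the lack of overlap, with adjusted p by edgeR from 0.0152 to 0.0354. NREP, LIMS2, EML5 and TPM1 have antisense annotations over their exons, and so do KIF20A, COL18A1, STARD4, SLC7A5 and LIF, named below with their lists.

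**Figure D2:**
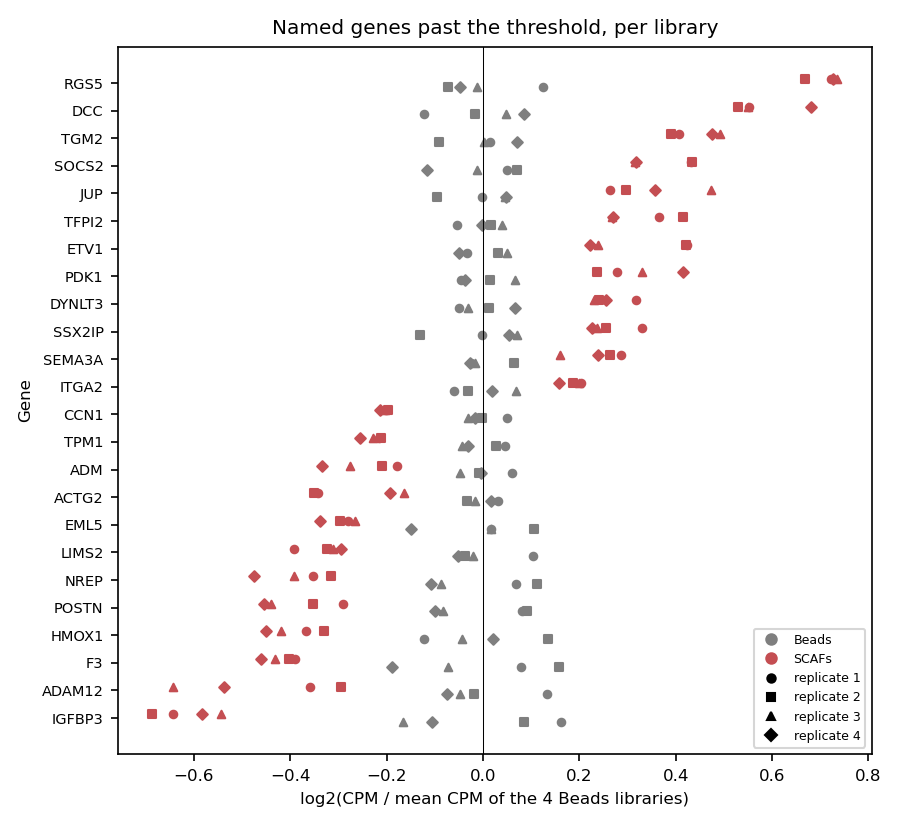
Named genes past the threshold, each on its own line, with log2 of CPM over the mean CPM of the 4 Beads libraries on the horizontal axis. Each point is a library, grey for Beads and red for SCAFs, with a symbol per replicate number, and the 4 SCAFs libraries of each gene lie to one side of its 4 Beads libraries. ARC, at under 1 CPM, is left out.

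Other genes called without the block were named after their values were seen. The amino acid transporter subunit SLC3A2 had a log2 change of -0.21 ± 0.035 and the activin antagonist FST one of -0.17 ± 0.029. CCDC80 (-0.21), ARSJ (-0.21) and RFLNB (-0.23) were lower too. The TGF-beta receptor TGFBR2 (0.16 ± 0.029) and the Wnt receptor FZD1 (0.24 ± 0.041) were higher. Adjusted p by edgeR ran from 0.016 to 0.038 for these 7 genes.

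A change of 2-fold or more was called for ARC alone without the block, an immediate early gene with counts of 1 to 5 in the Beads libraries and 9 to 19 in the SCAFs libraries. Summed over the groups these are 13 and 59 counts, a ratio of 4.54 (exact 95% Poisson interval 2.46 to 9.02, counting error only), with an adjusted p of 0.0398 by edgeR. The ARC level with Beads lay near that of 3 counts. With the block 5 genes passed 2-fold, named here after their values were seen: ARC (2.11) and the cyclin CCND2 (1.29) were higher, GIPR (-1.29), ADAMTS8 (-1.10) and FTH1P15 (-1.12) lower. Their average levels lay between -1.55 and -0.22 log2 CPM. FTH1P15 is a ferritin pseudogene and its value is uncertain because it shares sequence with its parent gene.

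Most genes of the NRF2 response to oxidants fell with the block. Of 25 genes tested, 0 rose and 18 fell with the block (0 and 22 adjusted over the list alone), against 0 and 1 without it (0 and 3 adjusted over the list alone). The multidrug transporter ABCC3 fell by 0.36 on the log2 scale with the block and ferritin light chain FTL by 0.21. The median over the members was -0.19 ± 0.043 (log2, mean and SD of 4 pairs), below 0 in 4 of 4 pairs. Camera gave an adjusted p of 3.00e-08 (block 2.47e-17), and adjusted p = 0.701 with an estimated correlation (block 0.513). The members were also lower in replicates 3 and 4 than in 1 and 2, with a median of -0.29. Within these sets the medians of SCAFs over Beads were -0.23 and -0.18. FTL has processed pseudogenes that can take part of its reads.

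Among matrix genes, too, more members fell than rose with the block. Among 23 collagens, 1 rose and 8 fell with the block (3 and 12 adjusted over the list alone), and none without it, also when adjusted over the list alone. The fibrillar collagen genes COL3A1 (-0.34 ± 0.023), COL1A1 (-0.26 ± 0.022) and COL5A1 (-0.27 ± 0.024) fell with the block, while COL13A1 (0.28) rose. COL13A1 and COL18A1 had adjusted p of 0.47 and 0.484 by edgeR without the block. The median over collagens was -0.14 ± 0.084 (camera adjusted p = 0.00178, and adjusted p = 0.71 with an estimated correlation, block 0.703). Of 39 other matrix and matrix assembly genes, 1 rose and 13 fell with the block (1 and 19 adjusted over the list alone), against 0 and 1 without it (0 and 5 adjusted over the list alone). POSTN, elastin ELN (-0.57 ± 0.058), the collagen chaperone SERPINH1 (-0.22 ± 0.023) and lumican LUM (-0.43 ± 0.053) were among them. Their median was -0.073 ± 0.028 (camera adjusted p = 3.55e-05, and adjusted p = 0.701 with an estimated correlation, block 0.513). Both lists were lower in replicates 3 and 4 than in 1 and 2, with medians of -0.21 and -0.13.

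Among targets of TGF-beta and of YAP, more members fell than rose with the block. Of 31 TGF-beta and myofibroblast genes, 2 rose and 12 fell with the block (3 and 14 adjusted over the list alone), against 0 and 1 without it (2 and 6 adjusted over the list alone). TGFBI (-0.25 ± 0.022), TPM1 and the contractile regulator LMOD1 (-0.27 ± 0.044) fell with the block and LTBP1 (0.17 ± 0.023) rose. The list's median was -0.077 ± 0.052 (camera adjusted p = 0.0159, and adjusted p = 0.687 with an estimated correlation, block 0.703). Of 24 YAP-TEAD targets, 1 rose and 10 fell with the block (2 and 13 adjusted over the list alone), against 0 and 3 without it (1 and 7 adjusted over the list alone). The 3 targets called without the block were IGFBP3, CCN1 and F3, and TGFB2 (-0.41 ± 0.069) fell and NT5E (0.19 ± 0.023) rose with it. The median was -0.075 ± 0.03 (camera adjusted p = 5.43e-04, and adjusted p = 0.54 with an estimated correlation, block 0.513). Both lists were also lower in replicates 3 and 4 than in 1 and 2, with medians of -0.072 and -0.081. Of the TGF-beta list 5 genes were called higher there and 12 lower, and of the YAP-TEAD list 6 and 13.

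Stress and sterol lists were called lower by camera, and neither call held with an estimated correlation. Of 30 unfolded protein and ER stress genes, 1 rose and 7 fell with the block (1 and 10 adjusted over the list alone), against 0 and 0 without it (0 and 3 adjusted over the list alone). The serine synthesis enzyme PHGDH and the amino acid transporter SLC7A5 stood at -0.17 and -0.22 without the block (adjusted p = 0.0891 and 0.21 by edgeR), and fell with it, as did the chaperone HSPA5 (-0.13 ± 0.023). Camera gave this list an adjusted p of 1.02e-04, and adjusted p = 0.406 with an estimated correlation (block 0.513), at a median of -0.069 ± 0.044. Of 24 cholesterol genes, 0 rose and 5 fell with the block (0 and 6 adjusted over the list alone), against 0 and 0 without it (0 and 1 adjusted over the list alone). INSIG1 (-0.23 ± 0.04) and HMGCS1 (-0.16 ± 0.033) fell with the block, and STARD4 stood at -0.16 without it (adjusted p = 0.21 by edgeR). The list's median was -0.067 ± 0.034 (camera adjusted p = 0.0159, and adjusted p = 0.905 with an estimated correlation, block 0.513). The cholesterol list was also lower in replicates 3 and 4 than in 1 and 2, with a median of -0.25, 0 genes called higher and 19 lower. The ER stress list had a median of -0.041 there, with 4 called higher and 12 lower.

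Mitotic genes made up the only list with a camera call upward, which did not hold with an estimated correlation. Of 40 tested, 6 rose and 1 fell with the block (15 and 1 adjusted over the list alone), and none without it, also when adjusted over the list alone. CCNB1 and KIF20A stood at 0.11 and 0.10 without the block (adjusted p = 0.692 and 0.342 by edgeR) and rose with it, while MYBL2 (-0.17 ± 0.034) fell. The median was 0.059 ± 0.064 and lay below 0 in replicate 3 (camera adjusted p = 0.00178, and adjusted p = 0.905 with an estimated correlation, block 0.703). Of 17 chemokines and cytokines, 0 rose and 2 fell with the block (0 and 3 adjusted over the list alone), against 0 and 0 without it (0 and 3 adjusted over the list alone). LIF and CXCL8 stood at -0.45 and -0.38 without the block (adjusted p = 0.226 and 0.232 by edgeR) and fell with it. The median was -0.034 ± 0.051, above 0 in replicates 1 and 2 (camera adjusted p = 0.0458, and adjusted p = 0.406 with an estimated correlation, block 0.513). Of the 13 mitochondrially encoded mRNAs, 0 rose and 6 fell with the block (0 and 9 adjusted over the list alone), and none without it, also when adjusted over the list alone. MT-ND1 and MT-CO2 stood at -0.11 and -0.087 without the block (adjusted p = 0.811 and 0.831 by edgeR). Their median was -0.087 ± 0.09, above 0 in replicate 2 (camera adjusted p = 0.0129, and adjusted p = 0.881 with an estimated correlation, block 0.703).

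Camera called 10 of 31 lists, 9 lower and 1 higher, and the same 10 with the block. None was called with an estimated correlation (lowest adjusted p = 0.406, with the block 0.513) or by fry for a common direction (lowest adjusted p = 0.116, with the block 0.0539). The mixed test of fry, for change in either direction, called 9 lists without and 23 with the block. Leaving out Beads 1 or SCAFs 4 left 4 calls, and 10 of the 35 splits of the libraries, the real one included, gave as many called lists. The other 9 divided the replicate sets unequally, and among the 18 splits with 2 libraries of each set per side the highest other count was 9.

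**Figure D3:**
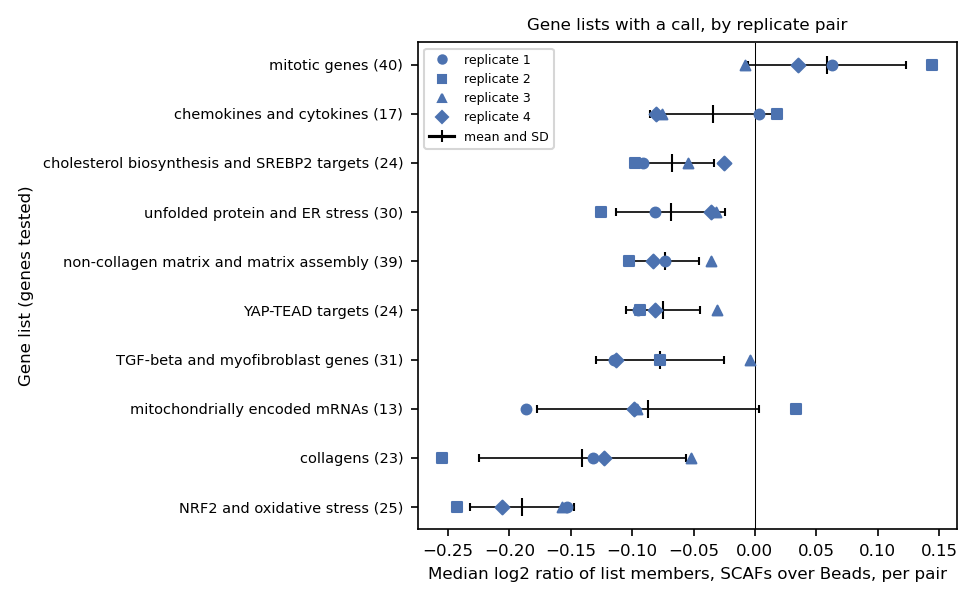
Median log2 ratio of SCAFs over Beads over the members of each of the 10 lists with a camera call, on the horizontal axis, with the number of genes tested after each name. Points are the 4 replicate pairs, and bars give their mean and SD. The NRF2 list lies between -0.24 and -0.15 in the 4 pairs.

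Secreted factors of senescent cells had no camera call, though some members changed with the block. Of 28 such factors, 5 rose and 3 fell with the block (5 and 7 adjusted over the list alone), against 0 and 1 without it (3 and 4 adjusted over the list alone), with a camera adjusted p of 0.592. The collagenase MMP1 rose by 0.68 on the log2 scale with the block, from 826 ± 142 CPM with Beads to 1319 ± 165 CPM with SCAFs (adjusted p = 8.82e-24 by edgeR, 0.232 without the block). STC1 (0.59 ± 0.029) and the plasminogen activator PLAT (0.31 ± 0.029) rose with the block too. Of 32 other senescence-associated genes, 4 rose and 0 fell with the block (4 and 0 adjusted over the list alone), against 1 and 0 without it (3 and 0 adjusted over the list alone), with cyclins CCND1 (0.36 ± 0.022) and CCND2 and cathepsin CTSB (0.10 ± 0.022) among those that rose (camera adjusted p = 0.23). Genes low in senescent cells gave 22 tested members, of which 1 rose and 0 fell with the block (6 and 0 adjusted over the list alone), and none without it, also when adjusted over the list alone, at a camera adjusted p of 0.177. The p53 targets gave 30, of which 4 rose and 1 fell with the block (4 and 1 adjusted over the list alone), against 0 and 0 without it (1 and 1 adjusted over the list alone), with PLK2 (-0.24 ± 0.028) lower and RRM2B (0.18 ± 0.031) higher (camera adjusted p = 0.0507). Among 40 S phase genes, 0 rose and 2 fell with the block (0 and 2 adjusted over the list alone), and none without it, also when adjusted over the list alone, at a camera adjusted p of 0.592.

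Adhesion and repair genes went both ways. Of 32 integrin and focal adhesion genes, 5 rose and 9 fell with the block (6 and 10 adjusted over the list alone), against 1 and 0 without it (1 and 2 adjusted over the list alone), with ITGA6 (0.39 ± 0.03) higher and ITGA1 (-0.35 ± 0.026) and ITGB3 (-0.37 ± 0.052) lower (camera adjusted p = 0.592). Wound healing and migration factors gave 34, of which 8 rose and 5 fell with the block (8 and 8 adjusted over the list alone), against 2 and 1 without it (4 and 1 adjusted over the list alone), and SEMA7A (0.24 ± 0.027) was among those that rose (camera adjusted p = 0.301). Among 24 metalloproteinases and inhibitors, 3 rose and 6 fell with the block (5 and 7 adjusted over the list alone), against 0 and 1 without it (3 and 1 adjusted over the list alone), with MMP14 (0.21 ± 0.022) and MMP16 (0.28 ± 0.038) higher (camera adjusted p = 0.7). For 32 immediate early genes, 2 rose and 4 fell with the block (3 and 5 adjusted over the list alone), against 1 and 0 without it (1 and 2 adjusted over the list alone), with EGR1 (-0.23 ± 0.031) and DUSP1 (-0.14 ± 0.028) lower (camera adjusted p = 0.895). In the hypoxia and glycolysis list of 29, 4 rose and 2 fell with the block (6 and 4 adjusted over the list alone), against 1 and 1 without it (1 and 2 adjusted over the list alone), with PDK1 higher and ADM lower (camera adjusted p = 0.25).

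Apart from the chemokines and cytokines above, inflammatory and innate immune lists had no camera call. Of 26 NF-kB targets, 1 rose and 2 fell with the block (1 and 3 adjusted over the list alone), and none without it, also when adjusted over the list alone, with VCAM1 (-0.47 ± 0.093) lower (camera adjusted p = 0.435). Of 31 interferon-stimulated genes, 0 rose and 3 fell with the block (0 and 3 adjusted over the list alone), and none without it, also when adjusted over the list alone, among them GBP1 (-0.20 ± 0.039) (camera adjusted p = 0.855). Antigen presentation gave 17 genes, of which 1 rose and 1 fell with the block (2 and 1 adjusted over the list alone), and none without it, also when adjusted over the list alone, at a camera adjusted p of 0.581. Phagocytic receptors gave 17, of which 2 rose and 2 fell with the block (2 and 2 adjusted over the list alone), against 0 and 0 without it (1 and 1 adjusted over the list alone), with GULP1 (0.21 ± 0.048) higher and AXL (-0.074 ± 0.022) lower (camera adjusted p = 0.895). In the lysosome list of 34, 1 rose and 1 fell with the block (3 and 1 adjusted over the list alone), and none without it, also when adjusted over the list alone, at a camera adjusted p of 0.592. For 20 LXR targets and lipid handling genes, 3 rose and 1 fell with the block (3 and 1 adjusted over the list alone), and none without it, also when adjusted over the list alone, with the lipid droplet gene PLIN2 (0.10 ± 0.027) higher (camera adjusted p = 0.3).

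Housekeeping lists had no camera call. Heat shock genes and chaperones gave 18 genes, of which none changed in either fit, also when adjusted over the list alone, at a camera adjusted p of 0.581. Nuclear genes of oxidative phosphorylation gave 37, of which none changed in either fit, also when adjusted over the list alone, at a camera adjusted p of 0.563. Ribosomal protein genes gave 76, of which 0 rose and 2 fell with the block (0 and 2 adjusted over the list alone), and none without it, also when adjusted over the list alone, at a camera adjusted p of 0.182. Metallothioneins and zinc transporters had 4 tested genes, too few for camera, of which 0 rose and 1 fell with the block (0 and 2 adjusted over the list alone), and none without it, also when adjusted over the list alone. Markers of other cell types showed no call without the block: of 7 epithelial markers, 1 rose and 0 fell with the block (1 and 1 adjusted over the list alone), and none without it, also when adjusted over the list alone, at a camera adjusted p of 0.896. Of 5 endothelial markers, none changed in either fit, also when adjusted over the list alone, at a camera adjusted p of 0.855. Macrophage and leukocyte markers had 2 tested genes of 20, of which none changed in either fit, also when adjusted over the list alone.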

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

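Chosen after the result was seen were the test of library size between the replicate sets, those of carried-over RNA and that of the axis between the sets. The GC and length tests and the counts over other splits of the libraries were set before their results were seen.

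DCC stood out in the SCAFs group, where SCAFs 4 had 12.3 CPM against 11.1 to 11.2 in the others (gap over range 0.852). SEMA3A stood out in the Beads group, where Beads 2 had 216 CPM against 203 to 205 (gap over range 0.890). These are 2 of 82 groups examined, where chance gives about 4.1.

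Replicates 1 and 2 differed from 3 and 4 with 3744 genes called. Total counts of the sets overlapped, with means of 30.9 and 33.6 M counts (exact permutation p = 0.371). With so few libraries this test cannot exclude a part for depth. After a per-library correction for GC content and transcript length, 90.9% of these genes were still called. GC content and transcript length, as corrected here, therefore do not account for the difference as a whole. The labels name no batch, culture or passage, so no biological explanation was tested. Whether the sets are library batches, culture states or days stays open.

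The NRF2, collagen and other matrix genes had a median log2 ratio of SCAFs over Beads, over 87 members, of -0.13 ± 0.04 over the pairs. RNA carried over from senescent cells might dilute mitotic transcripts at least as far, but no expression profile of these cells was at hand to check that. The mitotic median exceeded the NRF2 median by 0.25 ± 0.10, in 4 of 4 pairs. Both lists had already been called in these directions on the same libraries, so the sign was known beforehand. A rise of mitotic genes for another reason would hide dilution, and the matrix genes were not compared. The comparison therefore does not decide about carried-over RNA. After the GC and length correction the median was -0.12 ± 0.048. With the part proportional to the difference between the replicate sets removed, it was -0.089 ± 0.019 with slopes from the 6000 genes at 5 log2 CPM or more, and -0.11 ± 0.026 in a first version with slopes from all genes, below 0 in 4 of 4 pairs in both. A common slope per pair cannot remove a state of the cultures that affects these lists in particular, so such a state is not excluded. These tests leave a response to SCAFs as a hypothesis, beside a culture state, carried-over RNA and technical causes that were not tested.

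Genes higher with SCAFs might in part be RNA of the senescent cells themselves. The senescence-associated list had a median of 0.022 ± 0.026 over the pairs, above 0 in 3 of 4. By sign alone 18 of its members were higher and 14 lower without the block, while of those called with the block 4 rose and 0 fell. The donor cells are of the same line, so carried-over RNA and induced transcription cannot be told apart here for these genes.

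Without the block, 2 of the 35 splits of the 8 libraries gave as many genes changed as the real 33, so a chance split is not excluded by that count. The other split was the one between replicates 1 and 2 and replicates 3 and 4, with 2843 genes, which points to a structure of the samples. A split and its mirror swap the directions, so the larger direction of each other split was compared. The same 2 splits were as large for genes higher (15) and for genes lower (18), with 1513 in the larger direction of the other split, and for 2-fold changes (1, highest other 42). Among the 8 splits that part every pair, as the real one does, the highest other count without the block was 0. For called lists, 10 of 35 splits reached the real 10, with 15 as the highest other, so chance is not excluded by that count. The 9 other splits all divided the replicate sets unequally. Among the 18 splits with 2 libraries of each set per side, too few for a share under 0.05, the highest other was 9, and among the 8 that part every pair it was 8. With the block there are 8 such splits, too few for a share under 0.05: in 1, the real one, 834 genes changed (highest other 1), with 383 higher and 451 lower (1 in the larger direction of another split), 5 by 2-fold (0) and 10 lists (9).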

How the results depend on the processing

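Fits by replicate set, with a term for the sets, with the block in other tests or with a GC and length correction, and with the block lacking a replicate number were chosen after the data were seen; all others were planned. Genes changed (33, with 15 higher, 18 lower and 1 by 2-fold) numbered 834 with the replicate block (383, 451 and 5), 104 with DESeq2 (53, 51 and 0) and 191 without a filter on low counts (94, 97 and 4). At least 1 CPM in 4 libraries removed ARC and left 0 by 2-fold, since fewer genes were tested. With a term for the replicate sets 907 changed (434, 473 and 10), in replicates 1 and 2 alone 580 (261, 319 and 8), and in replicates 3 and 4 alone 356 (178, 178 and 4). With the block, limma-voom called 813 (373, 440 and 9), DESeq2 358 (147, 211 and 0), and the GC and length correction 893 (447, 446 and 5). Leaving out a library without the block gave 3 to 26 genes changed (3 to 12 higher, 0 to 14 lower, 0 to 0 by 2-fold), with fewer samples in the fit. Leaving out a replicate number with the block gave 607 (275, 332 and 6) without replicate 1, 661 (308, 353 and 13) without 2, 704 (308, 396 and 6) without 3 and 453 (207, 246 and 4) without 4. DESeq2 size factors, total counts, limma-voom and no robust estimation gave 33, 36, 36 and 32 calls, holding 33, 31, 33 and 29 of the 33 genes. Called lists (10) numbered 0 with an estimated correlation, 0 with fry, 0 and 0 with the block added to each, and 4 to 12 with a library left out. The block changed the call of IGFBP3 and brought past the threshold 11 of the 12 genes that the rule had named without a call. It changed no other call among the 37 genes named by the rule and no call of a called list, while other genes in the report passed only with it, MMP1 and STC1 among them. The GC and length correction in the same fit changed no call of a list. None of these 37 genes and no called list changed direction in any alternative that was run. P53 targets, not called in the planned fit, were called in 6 of 23 alternatives, genes low in senescent cells in 5, S phase genes, other senescence-associated genes and ribosomal proteins in 3 each, and antigen presentation and hypoxia genes in 1 each. The difference in total counts (-1.86e-04 M counts) changed sign without Beads 1 (1.42 M), Beads 3 (0.898 M) or SCAFs 1 (2.14 M), and ranged from -1.61 to 2.14 M. The causes were not tested except where fewer genes or samples are named. Depth limits genes near 3 counts per library, such as ARC.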

Other observations

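All tests of groups in this part were chosen after the results were seen, on the same libraries, and each gene group tested with camera was tested without its members among the 120 genes of smallest p in each direction in the fit with the replicate block.

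Of 30 genes of the smooth muscle contractile programme, 16 fell with the block and 0 rose, against 2 and 0 without it, with a median of -0.12 ± 0.042 over the pairs. With the block the cardiac actin ACTC1 fell by 0.60 on the log2 scale, the transcriptional coactivator MYOCD by 0.59 and calponin CNN1 by 0.22. Without it their adjusted p by edgeR was 0.514, 0.409 and 0.438, and the 2 genes called were TPM1 and ACTG2. The ACTC1 value is uncertain, like that of ACTG2, because actin paralogs share sequence. Of 33 amino acid response genes of the ATF4 type, 10 fell and 1, CHAC1 (0.15), rose with the block, against 1 and 0 without it. SLC3A2 and SLC7A5, which form an amino acid transporter, stood at -0.21 and -0.22, SLC1A4 at -0.25 and NUPR1 at -0.32. Among 25 ER chaperones and folding enzymes 5 fell, HYOU1 (-0.13) and HERPUD1 (-0.14) among them, and 1 rose with the block, and none changed without it.

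For the 22 contractile genes left without those seen first, camera with the block gave p = 3.77e-05, and p = 0.0571 with an estimated correlation. For the 29 ATF4 genes left it gave p = 3.47e-06 and p = 0.0209 with an estimated correlation, and for the 24 ER genes p = 0.00132 and p = 0.277. Of 12 pentose phosphate and ferritin genes 6 fell with the block, TALDO1 among them, and none without it, and all 6 were among the genes seen first. The remaining genes gave p = 0.443, and p = 0.489 with an estimated correlation, so the group rests on its called members. Adjusted over the 4 groups, limma's camera with an estimated correlation gave adjusted p = 0.0836 for the ATF4 genes left, adjusted p = 0.114 for the contractile genes left and adjusted p = 0.369 for the ER genes left, so none passed. A lower contractile and amino acid programme after SCAFs may be a hypothesis, and it rests on the preset correlation. Members of the lists fixed beforehand make up 9 of the 30 contractile genes, 12 of the 33 ATF4 genes, 18 of the 25 ER genes and 6 of the 12 pentose phosphate and ferritin genes, so these groups are not independent of those lists.

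Receptors and ligands of the axon guidance families changed in both directions: SEMA3A, SEMA7A, DCC, NRP1 and PLXNA2 rose with the block, and SLIT2, NTN4, EFNB2, EPHA4, EFNA5 and SEMA6A fell. Only SEMA3A and DCC were called without the block. PLXNA2 stood at 0.34 and NTN4 at -0.36. The 11 genes are 20% of 55 tested, against 5.61% of other genes. The family was tested in 3 versions. The versions that hold the genes seen first restate them in part: over all members Fisher's exact p was 2.17e-04, and among those at 4 log2 CPM or more (7 of 26) it was 0.00612. Without the genes seen first, 5 of 49 were called against 4.08% of others, with Fisher's exact p = 0.0494, the highest of the 3 versions and close to the threshold. A wider response of these families may therefore be a hypothesis with weak backing.

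An interaction test in edgeR (adjusted over all genes) called 25 genes for a different change with SCAFs between the replicate sets. Genes are named here after their values were seen. The test takes its error from the spread within the sets, so its p-values may be too small if libraries of a set share a culture. With 2 sets it does not show how the response varies between cultures. Decorin (DCN) stood at -0.50 in replicates 1 and 2 and -0.15 in replicates 3 and 4 (adjusted p = 1.36e-07). The cell cycle inhibitor CDKN1A stood at -0.024 and 0.21 (adjusted p = 5.62e-04), and the IGF-binding genes IGFBP4 and IGFBP5 at -0.14 and 0.10, and at -0.19 and 0.08. Across genes, which are not independent replicates, the changes within the sets had a Spearman correlation of 0.172 over all genes and 0.409 over the 6000 at 5 log2 CPM or more. Across these 6000 genes the treatment difference and the difference between the sets had a Pearson correlation of 0.363, within the range of -0.314 to 0.426 that the other splits parting every pair gave. Over all genes it was 0.133, against -0.106 to 0.128 for those 7 splits, which are too few for a share under 0.05.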
